A study of Rattus norvegicus with 43 samples.

How the data were processed

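Gene expression was measured in the colonic mucosa of male Sprague Dawley rats, described as weanling, that were fed corn oil, fish oil or olive oil and injected with azoxymethane, a colon carcinogen, at 15 mg/kg. That word cannot hold for the late rats when their tissue was taken, 10 wk after injection by their labels. The labels place each rat 12 h or 10 wk after injection, while the treatment protocol in the labels describes a repeat injection for the late rats and counts their interval from it. The late groups are called 10 wk here, as each sample's own label does, and age, number of injections and time on diet differ between the time points together. RNA was hybridised to 1-colour CodeLink arrays, 43 in all, from 29 rats in 6 groups, and 10 rats had repeat arrays, 14 of them. Each rat is a separate animal, and the p-values measure the spread between rats of a group. That spread holds differences between animals, between the scans of their arrays, and between single and averaged arrays. No untreated or reference RNA was included.

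Each array's file holds spot intensity, local background and derived columns for 8452 probes, per the file headers, and 1 file holds 8449. The quantification software is not given in the sources used here. Missing spots carry the code -9999 (9 to 119 per array, median 30). The quality flag column reads good for every spot and could not be used. The authors' background-subtracted intensity equals spot mean minus background median, except that 1 constant per diet stands in its place on 1966 corn oil, 1559 fish oil and 1227 olive oil probes, on all arrays of that diet. The deposited normalized intensity is that column divided by 1 number per array, with a median of 1.04 to 1.06 per array apart from 2.02 in rat 131, and carries the same constants. How that number was chosen is not given in the sources used here. In the series-wide table of these values, 15 neighbouring probes are shifted by 1 position on late olive oil arrays, so each array's own file was used. The least processed intensity columns, spot mean and background median, were therefore used, and the deposited normalized values only as an alternative. No further scaling was applied in that alternative, so rat 131 lies higher in it than the other rats.

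Background was corrected by normexp with an offset of 50, and arrays were quantile normalized on the linear scale in limma 3.58.1 under R 4.3.3. Values below the 10th percentile of the normalized distribution were set to it, a log2 level of 6.46, and log2 was taken. Repeat arrays of a rat were averaged to 1 value per rat. Levels at that floor have no order. A probe was tested if it lay above the 30th percentile in at least 4 rats, which left 6378 probes (75.5%). The percentile had been laid down for files with no flag column. It replaced the scanner flag here because that flag read good for every spot and would have removed no probe. Precision is limited by the number of rats, 4 or 5 per group. Median signal above background ranged from 163 to 685 per array, and 84.8% to 99.8% of spots reached the scanner's noise level.

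The platform annotation gave 6252 probes 1 gene symbol, 75 several and 2125 none. No symbol needed updating, and 4429 named genes were tested. Where a gene has several probes, the probe with the highest mean over all rats stands for it in gene lists and among named genes, and probes that go the other way are stated.

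All 6 groups entered 1 limma fit (lmFit and eBayes) with 23 residual degrees of freedom and a prior of 4.17. Contrasts compared pairs of diets at each time, 10 wk with 12 h within each diet and averaged over diets, and the diet differences between times. Moderated F tests covered the diets at each time and the diet by time interaction. Every adjusted p is limma's with the Benjamini-Hochberg method over all tested probes, and 0.05 was the threshold. Errors beside log2 differences are standard errors of the fit, and errors beside levels are standard deviations between rats.

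Gene lists, 28 with 541 members, were fixed before the data were examined. Their names are shortened in the text. The fatty acid oxidation list also holds PPAR targets, the unfolded protein response list amino acid response genes, and the immediate early list heat shock genes. The arrays carry 294 members and 244 were tested. Each list was tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, which asks whether the list's genes move on balance 1 way and does not compare them with other genes. Adjusted p-values of lists are over the 28 lists within a contrast. With an estimated correlation no list passed in any contrast. Spots missing for a rat were filled with the mean of its group in the list tests alone.

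The genes named were chosen by a rule laid down before the data were examined. For the time contrast averaged over diets it takes the 8 largest rises and 8 largest falls past the threshold, and up to 4 members of each list that passes camera or has at least 3 members past the threshold. For pairs of diets with few calls it takes every gene that passes and the 3 with the smallest p in each direction. A fixed panel of genes was to be given in every diet contrast, and its members Cpt1a, Mgmt and Cdkn1a passed the filter. Other members of the panel are not reported here.

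The files give no slide or scan date, so that planned block was not run. Spot area, background ring area and background level separate the arrays into 4 scan classes, found after the data were seen. They are called large spots (7 arrays), small ring (13), large ring (17) and high background (6). The small ring class holds 11 rats at 12 h and 1 at 10 wk, the large ring class 3 and 11, and the large spots class 4 and 2. The 6 high-background arrays are repeats of late corn oil rat 136 and late fish oil rat 236. Fits with scan class as a block used all 43 arrays with the rat as a random block, and their standard errors are approximate for probes with missing spots. Values within a scan class are differences of means over the rats it holds.

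Alternatives were median scaling, a lower floor, no or a stricter probe filter, the first array of each rat alone, all arrays with the rat as a random block, array quality weights, variance trend with robust moderation, the deposited normalized values, fits of the compared groups alone, and leaving out each rat in turn. The fit was tested on simulated data, 6378 probes with 100 changed at each size. It recovered 54 of the 100 changed by 0.5 on the log2 scale and 95 of those changed by 1 in the 12 h fish oil and corn oil comparison, 49 and 93 in the late one, and 86 and 98 for time averaged over diets. Unchanged probes gave 4, 7 and 9 false calls in that order. The simulated probes varied independently, without scan classes or a floor, so these counts do not give the recovery or the false calls in the real arrays.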

Results

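Expression in the colonic mucosa was compared between rats fed corn oil, which is rich in linoleic acid, fish oil, which carries long-chain polyunsaturated fatty acids of marine origin, and olive oil, which is rich in oleic acid. All rats had received azoxymethane, which is metabolised to a DNA-methylating agent and induces colon tumours in rodents. The series title frames the 2 time points as the initiation and progression stages of colon cancer and asks how diet modifies the expression signature of each. At 12 h there were 5 rats per diet. At 10 wk there were 5 corn oil, 4 fish oil and 5 olive oil rats. With repeats, the 6 groups held 7, 7, 6, 8, 8 and 7 arrays in that order of time and diet. Arrays differed in scan class as well as in group, and repeat arrays of a rat lay closer within a class (median SD of their log2 difference 0.139) than across classes (0.482). Arrays of different rats of a group gave 0.332 within a class and 0.502 across classes.

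**Figure D1:**
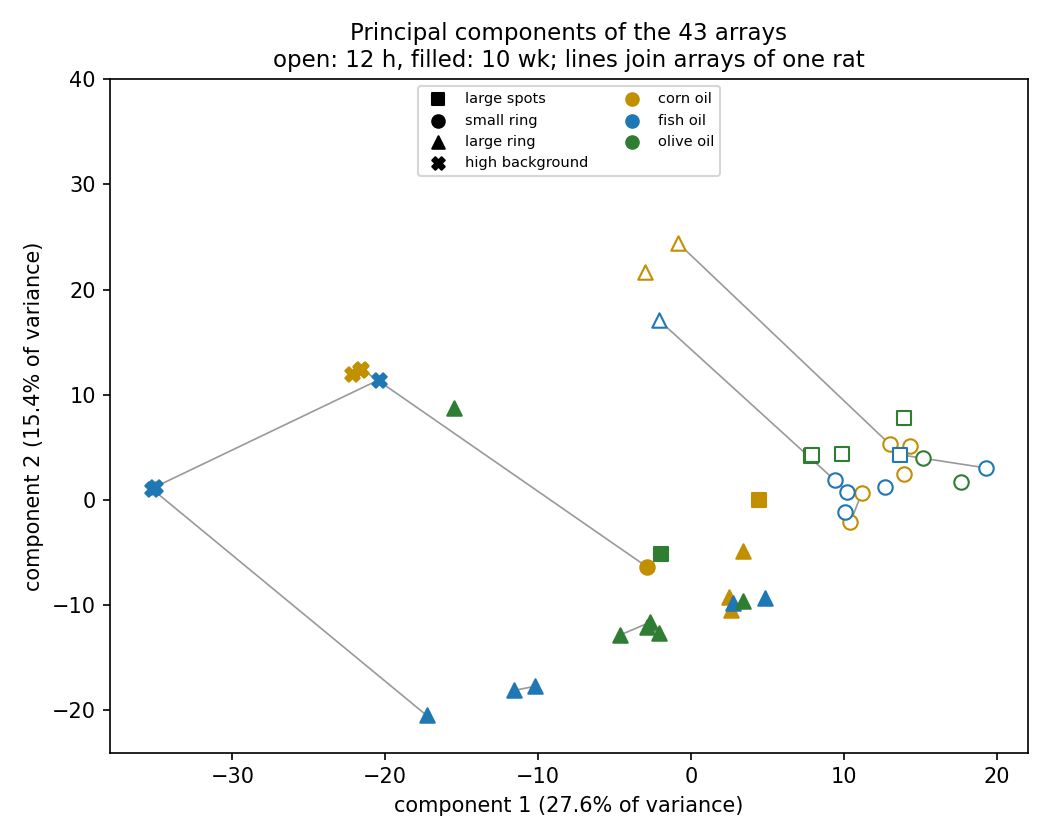
Principal components of the 43 arrays over the tested probes, with component 1 (27.6% of the variance) on the horizontal axis and component 2 (15.4%) on the vertical axis. Colours mark diets, open symbols 12 h, filled symbols 10 wk, shapes the scan class, and lines join arrays of 1 rat. The 6 high-background arrays lie at component 1 scores of -20.4 or below.

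Of the comparisons made, 10 wk against 12 h gave the most differences. Phlda3, a p53-induced inhibitor of Akt signalling, fell by 1.78 (SE 0.17) on the log2 scale, 3.44-fold, from 8.88 ± 0.64 (n = 15) at 12 h to 7.11 ± 0.15 (n = 14) at 10 wk (adjusted p = 5.11e-08), and all 14 late rats lay below the 12 h mean. The chemokine genes Cxcl10 and Cxcl11, both inducible by interferon, fell by 1.80 (SE 0.24, adjusted p = 4.09e-06) and 1.26 (SE 0.11, adjusted p = 1.95e-08). Trpv6, the apical calcium channel of the intestinal epithelium, fell by 1.36 (SE 0.14), from 11.45 ± 0.48 to 10.10 ± 0.24, and S100g, the cytosolic calcium carrier calbindin, fell by 1.31 (SE 0.24). Among the genes that rose, the bile acid transporter gene Slc10a1 was higher by 1.27 (SE 0.20), the Wnt modulator gene Sfrp2 by 1.17 (SE 0.27) and Fabp6, which encodes a bile acid binding protein, by 0.99 (SE 0.23, 1.99-fold). Ankrd10 had the smallest adjusted p, 3.38e-09, with a rise of 0.99 (SE 0.08) from 11.33 ± 0.23 to 12.31 ± 0.20.

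The remaining genes taken by size were Zmiz1, Clic4 and Ccnd2, which were lower at 10 wk by log2 differences of -1.44, -1.32 and -1.27, and Cfap141, Pdia5 and Nrbp2, which were higher by 1.13, 1.07 and 1.03. Cd36 was taken by size too, at a fitted difference of 1.39 that depends on the floor. Ccnd2 encodes a G1 cyclin and Cd36 a fatty acid transporter. Cd36 passed at adjusted p = 0.0486, with levels of 8.85 ± 1.55 against 7.49 ± 1.59 and 9 of the 14 late rats above the 12 h mean. At 12 h 2 corn oil, 3 fish oil and 4 olive oil rats lay at the floor, and at 10 wk 1, 0 and 1, so that its size and its place among the largest rises are not measured. For Slc10a1, Sfrp2, Fabp6, Nrbp2 and Tagln at 12 h, and for Clic4 and Bak1 at 10 wk, some arrays lay at the floor on the lower side alone. There the floor can only have made the fitted differences smaller in size, while other settings, such as scan class as a block, can still give smaller ones. The Cd36 spot was above noise on 13 of the 20 arrays at 12 h, another Cd36 probe gave -0.13 (adjusted p = 0.136), and with scan class as a block the difference was 2.16 (adjusted p = 0.00559). In the deposited normalized values, where constants stand in for this probe, Cd36 gave -0.20. Further probes for Slc10a1 (-0.19, adjusted p = 0.138) and Clic4 (0.20 and -0.25) did not pass, and with scan class as a block Clic4 dropped to -0.68 (adjusted p = 0.189).

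In all, 2355 of 6378 probes differed between 10 wk and 12 h averaged over diets, 1226 higher and 1129 lower at 10 wk, and these included 1630 named genes. At an unadjusted p under 0.05 there were 2943 probes, where 318.9 would fall by chance. Scan class differed between the times. With it as a block 2049 probes passed, 1547 of them among the 2355 with the same sign, and 2315 of the 2355 kept their sign. Within the large spots class (2 late and 4 early rats) 91.2% of the called probes had the same sign, within the small ring class (1 and 11 rats) 85.9% and within the large ring class (11 and 3 rats) 95.1%. These probes were called with the rats of each class included. Of the 2324 probes called without the 6 rats that have large spots arrays, 85.2% had the same sign within that class, against 62.2% of the probes not called. Without the 6 high-background arrays 2466 probes passed.

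Targets of p53, the DNA damage regulator, fell as a list. Of 13 measured members, 7 fell and 1 rose (9 and 1 adjusted over the list alone), with a list median of -0.22 (camera adjusted p = 0.0159). The list did not pass at adjusted p = 0.109 with an estimated correlation. Besides Phlda3, cyclin G1 (Ccng1) fell by 1.08 (SE 0.15, 2.12-fold, adjusted p = 7.21e-06), the kinase gene Plk2 by 0.53 (SE 0.10) and the nuclease gene Aen by 0.44 (SE 0.09). Cdkn1a, which encodes the p21 inhibitor of cyclin-dependent kinases, fell by 0.26 on the probe used here (adjusted p = 0.00121) and by 0.76 on another (adjusted p = 0.000975). Of the late rats, 14 of 14 lay below the 12 h mean for Ccng1, Plk2 and Aen. With scan class as a block the list's adjusted p was 0.000824, and its median was -0.22, -0.16 and -0.34 within the large spots, small ring and large ring classes.

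Genes of xenobiotic and antioxidant metabolism fell as a list too, with 9 of 18 measured members lower and none higher (9 lower and 1 higher adjusted over the list alone) and a median of -0.27 (camera adjusted p = 0.0472). The call was lost at adjusted p = 0.111 with an estimated correlation. The sulfotransferase gene Sult1b1 fell by 0.63 (SE 0.09), the cytochrome P450 gene Cyp3a9 by 0.41 (SE 0.08), the glutathione transferase gene Gstm1 by 0.51 (SE 0.13) and the epoxide hydrolase gene Ephx1 by 0.28 (SE 0.07). For these genes 13 or 14 of the 14 late rats lay below the 12 h mean. The block gave adjusted p = 0.0328 for the list, and medians within the 3 classes were -0.06, -0.20 and -0.31.

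Lipogenic genes rose, 5 of 9 measured members and none lower (5 and 0 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.0472, and adjusted p = 0.109 with an estimated correlation). Fasn, which encodes fatty acid synthase, rose by 0.48 (SE 0.08, 1.40-fold, adjusted p = 9.38e-05), from 9.59 ± 0.20 to 10.07 ± 0.23, and every late rat lay above the 12 h mean. Acaca, which encodes acetyl-CoA carboxylase, rose by 0.44 (SE 0.08), Acly, which encodes ATP citrate lyase, by 0.34 (SE 0.10) and Acsl3 by 0.32 (SE 0.08). The list did not pass with scan class as a block (adjusted p = 0.0789), while its median was 0.21, 0.25 and 0.29 within the classes.

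**Figure D2:**
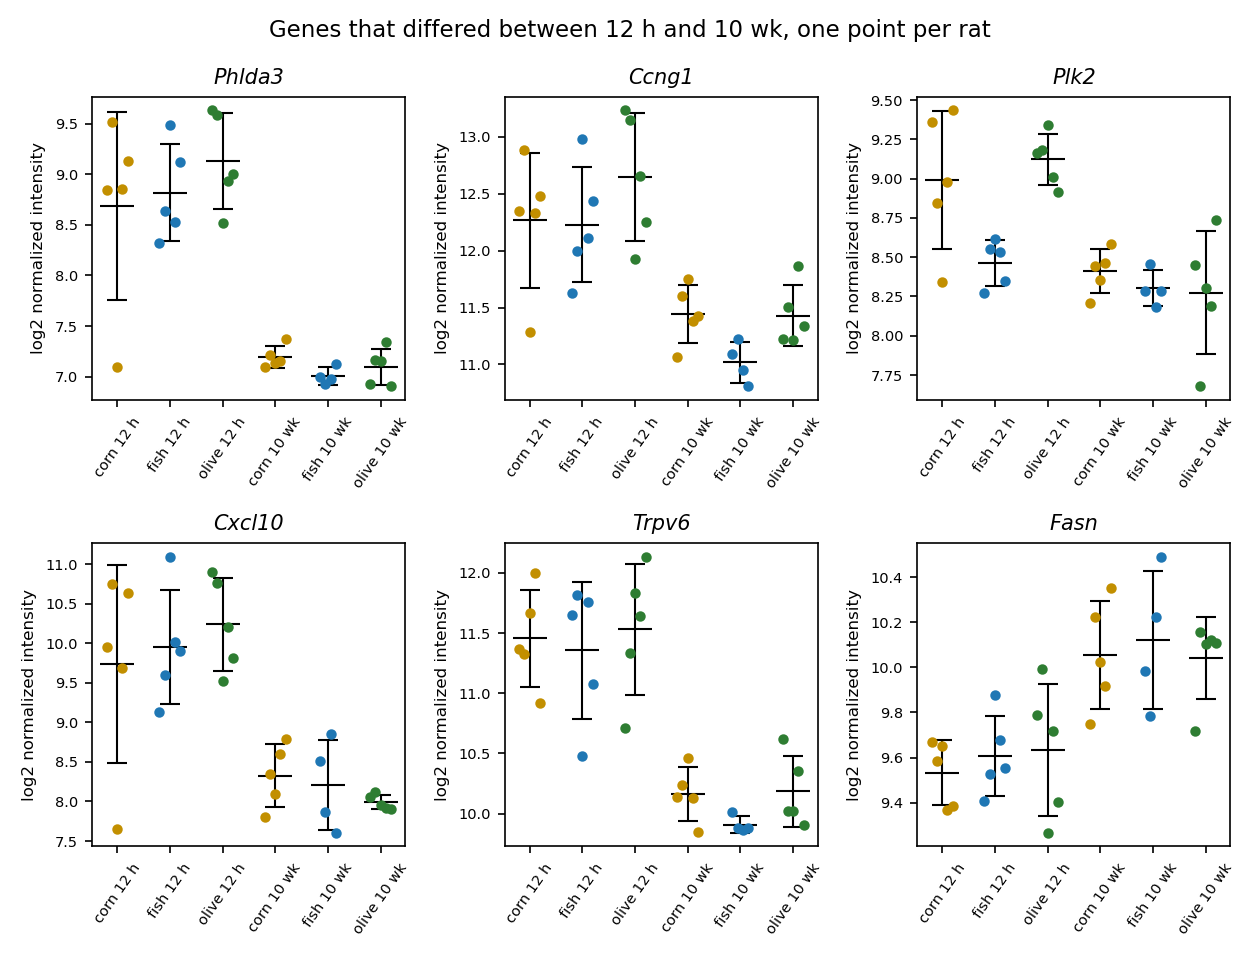
Log2 normalized intensity (vertical axes) of the p53 targets Phlda3, Ccng1 and Plk2, of Cxcl10 and Trpv6, and of Fasn in the 6 groups of diet and time (horizontal axes), 1 point per rat, with the mean and SD of each group as bars. Phlda3 lies at 7.11 ± 0.15 over the 14 late rats, and 1 corn oil rat at 12 h shares that level.

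None of the other fixed lists passed camera. In the cell cycle list 4 of 9 members rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.271). The mitotic kinase gene Cdk1 rose by 0.52, the proliferation marker gene Mki67 by 0.60 and the cyclin gene Ccna2 by 0.53, while Tyms, which encodes thymidylate synthase, fell by 0.37. Of 6 apoptosis regulators 3 fell (3 adjusted over the list alone, camera adjusted p = 0.157), Mcl1 by 0.46, Bak1 by 0.79 and Casp9 by 0.19, and Tnfrsf1a stood at -0.07 (adjusted p = 0.516). Mcl1 opposes apoptosis, and Bak1 and Casp9 promote it. Of 6 immediate early and heat shock genes 4 fell (4 adjusted over the list alone, camera adjusted p = 0.0694), Jun by 0.34, Zfp36 by 0.38, Ier2 by 0.21 and Junb by 0.22. The call of Jun was lost with scan class as a block (-0.04, adjusted p = 0.819) and that of Junb under median scaling (adjusted p = 0.0597).

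In the colonocyte list 3 of 10 members fell and 1 rose (3 and 1 adjusted over the list alone, camera adjusted p = 0.362). The epithelial transcription factor gene Klf4 fell by 0.46 (SE 0.08, adjusted p = 7.22e-05), Cdhr5 by 0.29 and Ceacam1 by 0.33, and the steroid dehydrogenase gene Hsd11b2 rose by 0.26. Under the scan class block Cdhr5 stood at -0.09 (adjusted p = 0.416) and Hsd11b2 at 0.24 (adjusted p = 0.061). Of 12 eicosanoid genes 3 fell and 1 rose (3 and 1 adjusted over the list alone, camera adjusted p = 0.271). Alox5, which encodes the lipoxygenase that starts leukotriene synthesis, fell by 0.38 (SE 0.08, adjusted p = 0.000524). The cyclooxygenase gene Ptgs1 fell by 0.34, the prostaglandin dehydrogenase gene Hpgd by 0.20 and the prostaglandin receptor gene Ptger4 rose by 0.24, but with the block these stood at -0.18, -0.01 and 0.12, with adjusted p-values of 0.0903, 0.915 and 0.415.

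Smooth muscle genes were higher at 10 wk in 3 of 5 members (3 adjusted over the list alone, camera adjusted p = 0.227). Myh11 rose by 0.59 (SE 0.16), Smtn by 0.30 and Tagln by 0.48, and Cnn1, with rats at the floor at both times, stood at 0.39 (adjusted p = 0.251). The list's median was 0.35, -0.20 and 0.15 within the large spots, small ring and large ring classes, and the calls of Tagln with the block (adjusted p = 0.092) and of Smtn under median scaling (adjusted p = 0.0699) were lost. Of 16 ribosomal protein genes 5 rose (5 adjusted over the list alone, camera adjusted p = 0.0504). Rps3a, Rps18, Rpl21 and Rps19 rose by 0.26, 0.23, 0.23 and 0.30. In the deposited normalized values, where constants stand in for their probes, Rps3a, Rps18 and Rps19 each gave -0.20, and under median scaling Rps3a, Rps18 and Rps19 did not pass, with adjusted p-values of 0.178, 0.0662 and 0.227. With the block, Rps3a (adjusted p = 0.0921) and Rps19 (adjusted p = 0.304) did not pass. Of 5 clock genes, Nr1d2 fell by 0.54 (SE 0.10), Dbp by 0.33 and Bmal1 rose by 0.22 (2 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.503), and Bhlhe40 stood at -0.12. Dbp did not pass with the block (adjusted p = 0.153) nor Bmal1 under median scaling (adjusted p = 0.0843). The hour of tissue collection is not given.

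Of 18 fatty acid oxidation genes and PPAR targets, the uncoupling protein gene Ucp2 fell by 0.38 and the dehydrogenase gene Acadl by 0.24, Cd36 was the 1 that rose, and Slc25a20 stood at -0.25 (adjusted p = 0.0611). Over that list alone 2 fell and 0 rose (camera adjusted p = 0.577). Adjusted over the list alone, both goblet cell genes fell, 2 Wnt targets rose, and 2 genes each of acute inflammation and of the unfolded protein response fell. Camera did not call cholesterol synthesis (adjusted p = 0.794), Wnt targets (0.271), DNA repair (0.669), unfolded protein response (0.271), oxidative phosphorylation (0.669), interferon response (0.859) or acute inflammation (0.271). Cell type markers did not pass as lists either, with 0.378 for goblet cells, 0.759 for enteroendocrine cells, 0.947 for fibroblasts, 0.775 for B cells, 0.271 for T and NK cells, 0.503 for macrophages, 0.669 for endothelium, 0.915 for adipocytes and 0.292 for enteric neurons and glia. In the interferon list the median was -0.01 while the mean was 0.01 and the test pointed up. By fry, 15 of the 28 lists moved on balance in 1 direction.

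Several of these calls were lost when 1 rat was left out. The Cd36 call was lost without rat 102, 103, 104, 131, 132, 135, 201, 202, 203, 205, 232, 233, 234, 301, 302, 305, 306, 332, 334 or 336, each left out alone, with adjusted p-values of 0.0595 to 0.0836. The Junb call was lost without rat 102, 105, 106, 131, 135, 136, 201, 202, 206, 234, 236, 301, 304, 305, 334, 335 or 336 (0.0529 to 0.0974), and the Hpgd call without rat 105, 106, 135, 136, 201, 202, 205, 234, 236, 304, 305, 306, 334, 335 or 336 (0.0504 to 0.0845). The Rps19 call was lost without rat 105, 106, 136, 202, 234, 236, 304, 306 or 335 (0.0543 to 0.0771), and the Bmal1 call without rat 104, 135, 205, 232, 233, 302, 305, 332 or 336 (0.0505 to 0.0575). Without rat 234, Tagln stood at an adjusted p of 0.053 and Rpl21 at 0.0526. Slc25a20 passed without rat 106, 203, 233, 301 or 302 (0.01 to 0.0483). The xenobiotic list was lost without rat 102, 134, 201, 206, 233 or 306 (0.0503 to 0.0575), and the lipogenic list without rat 102, 106, 131, 134, 201, 202, 206, 233, 304, 306 or 333 (0.0503 to 0.0623). The ribosomal list passed without rat 103, 104, 132, 135, 203, 205, 232, 301, 302, 305, 332 or 336 (0.0212 to 0.0479), and the immediate early list without rat 103, 232 or 302 (0.0395 to 0.0484). Both also passed with the mean of a gene's probes (0.0434 and 0.0491).

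The deposited normalized values without the replaced probes did not call 12 of the genes named above. Ucp2 (-0.34, adjusted p = 0.0569), Acadl (-0.26, adjusted p = 0.129), Casp9 (-0.12, adjusted p = 0.385), Ephx1 (-0.21, adjusted p = 0.183) and Ceacam1 (-0.28, adjusted p = 0.129) were among them. The others were Cdhr5, Dbp, Bmal1, Jun, Junb, Zfp36 and Ier2, with adjusted p-values of 0.0511 to 0.304. Where constants stand in for the probe in at least 1 diet, Sfrp2, Clic4, Acsl3, Ptger4, Hpgd, Cdk1, Smtn and Rpl21 were not called in the deposited values either (0.0546 to 0.898). With the first array of each rat the calls of Bmal1, Hpgd, Ptger4, Rps18 and Rps19 were lost (0.066 to 0.097) and Slc25a20 passed (0.0375). With array quality weights Hsd11b2, Rpl21, Rps18 and Rps19 were lost (0.0667 to 0.101), and with the rat as a random block Cd36, Junb and Tagln (0.0503 to 0.0807). Cd36 was lost too without a filter on dim probes (0.0684) and with trend and robust moderation (0.058).

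**Figure D3:**
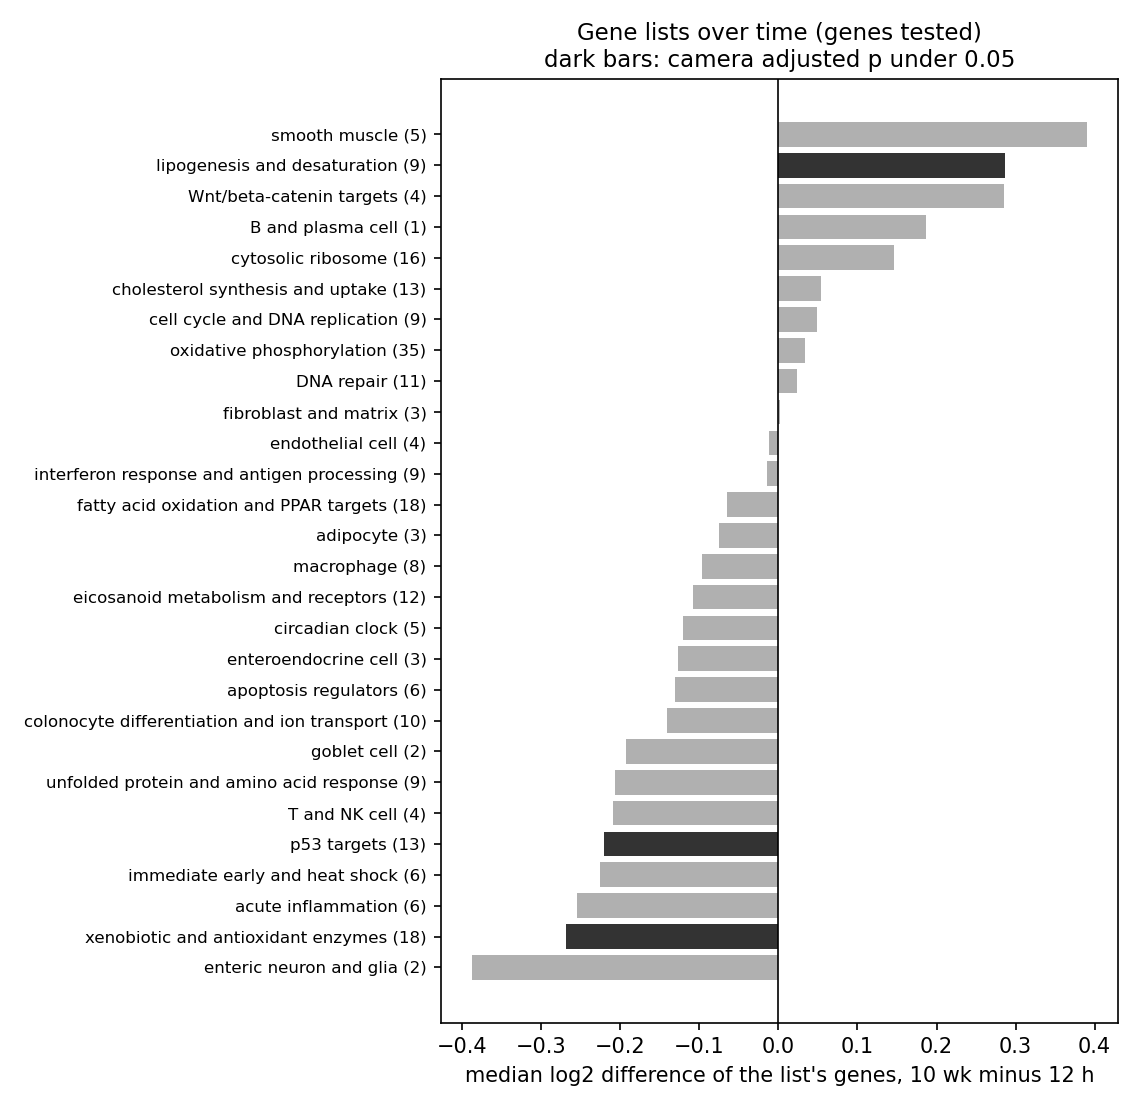
Median log2 difference, 10 wk minus 12 h averaged over diets (horizontal axis), of the tested genes in each of the 28 lists (vertical axis, number of tested genes in parentheses). Dark bars mark the 3 lists past camera's threshold, p53 targets at -0.22, xenobiotic enzymes at -0.27 and lipogenesis at 0.29.

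Within each diet the p53 target Phlda3 fell by 1.49 in corn oil (adjusted p = 0.00483), fell by 1.81 in fish oil (adjusted p = 0.00064) and fell by 2.04 in olive oil rats (adjusted p = 0.000167). Cxcl10 fell by 1.74 in fish oil (adjusted p = 0.0115) and by 2.25 in olive oil rats (adjusted p = 0.00145), and stood at -1.41 in corn oil rats (adjusted p = 0.0557). Mki67 rose by 1.12 in olive oil rats (adjusted p = 0.00145) and stood at 0.50 in corn oil (adjusted p = 0.176) and 0.20 in fish oil rats (adjusted p = 0.591). The differences between diets in these changes did not pass for any of the 3 genes, with adjusted p-values of 0.796 to 0.996.

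Time changed 193 probes in corn oil rats (96 higher, 97 lower), 776 in fish oil rats (397 and 379) and 852 in olive oil rats (501 and 351). In corn oil rats, p53 targets were lower (1 of 13, 6 adjusted over the list alone, camera adjusted p = 0.0227, and adjusted p = 0.123 with an estimated correlation), as were immediate early genes (adjusted p = 0.0314, and adjusted p = 0.386 with an estimated correlation) and T and NK cell markers (adjusted p = 0.0373, and adjusted p = 0.422 with an estimated correlation), while lipogenesis was higher (adjusted p = 0.0314, and adjusted p = 0.123 with an estimated correlation). Adjusted over the list alone, 2 lipogenic genes were higher, 1 T and NK cell gene was lower and 0 immediate early genes passed. None of these 4 passed with scan class as a block. Under median scaling immediate early genes and T and NK cell markers did not pass (adjusted p = 0.0502 each), while oxidative phosphorylation, lower, did (adjusted p = 0.0221). In olive oil rats, p53 targets were lower (5 of 13, 8 adjusted over the list alone, adjusted p = 0.00338, and adjusted p = 0.0901 with an estimated correlation). There, apoptosis regulators (adjusted p = 0.0466, and adjusted p = 0.404 with an estimated correlation) and xenobiotic enzymes (adjusted p = 0.0451, and adjusted p = 0.225 with an estimated correlation) were lower too. Cell cycle genes (adjusted p = 0.0153, and adjusted p = 0.404 with an estimated correlation) and ribosomal protein genes (adjusted p = 0.00604, and adjusted p = 0.404 with an estimated correlation) were higher. Adjusted over the list alone, 4 apoptosis regulators and 7 xenobiotic enzymes were lower (1 xenobiotic enzyme higher), 4 cell cycle genes were higher (1 lower) and 3 ribosomal protein genes were higher. With scan class as a block apoptosis regulators did not pass (adjusted p = 0.0695), and under median scaling lipogenesis, higher, passed (adjusted p = 0.043). In fish oil rats no list passed camera, and 4 did by fry, while with scan class as a block p53 targets (adjusted p = 0.0386) and xenobiotic enzymes (adjusted p = 0.0399) were lower. In corn oil rats the count was 92 without rat 102, 65 without rat 103, 89 without rat 105, 124 without rat 106, 97 without rat 135 and 111 without rat 136. It was 338 without rat 234 and 353 without rat 236 in fish oil rats, and 522 without rat 305, 456 without rat 334 and 512 without rat 336 in olive oil rats. With scan class as a block 836 probes passed in corn oil and 566 in olive oil rats. Of the lists in corn oil rats, lipogenesis was lost without rat 132 (adjusted p = 0.055), immediate early genes without rat 105, 106, 132 or 136 (0.055 to 0.104) and T and NK cell markers without rat 102, 104, 132, 134 or 136 (0.0584 to 0.154). Macrophage markers, lower, passed there without rat 106 (adjusted p = 0.0452) or 131 (0.0174), and smooth muscle genes, higher, without rat 136 (0.0312). Of the lists in olive oil rats, apoptosis regulators were lost without rat 304, 305, 306, 333, 334 or 335 (0.0564 to 0.117), xenobiotic enzymes without rat 304, 306, 332 or 334 (0.0503 to 0.111), cell cycle genes without rat 304 (0.0531) and ribosomal protein genes without rat 306 (0.101). Immediate early genes, lower, passed there without rat 302 (0.0478).

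At 12 h, the gene with the smallest p among those higher in fish oil than in corn oil rats was Fabp4, which encodes a fatty acid binding protein of adipocytes and macrophages. It lay at 8.06 ± 0.48 (n = 5) against 6.75 ± 0.27 (n = 5), a log2 difference of at least 1.31 (SE 0.25, at least 2.48-fold, adjusted p = 0.126), with all 5 fish oil rats above the corn oil mean, and did not pass. Its spot was above noise on 4 of the 7 corn oil arrays, and 1 of the 5 corn oil rats and none of the fish oil rats lay at the floor. Within the small ring class (5 and 4 rats) the difference was at least 1.15 and within the large ring class (1 and 2 rats) at least 1.23. Next were Rgs4, a regulator of G protein signalling, at 1.40 (SE 0.34, adjusted p = 0.268), and Gfpt2 at 0.55 (adjusted p = 0.373). Rgs4 was above noise on 2 of the 7 corn oil arrays, and 3 of the 5 corn oil rats and 1 of the 7 fish oil arrays lay at the floor, so that 1.40 is neither an exact size nor a bound. It was at least 1.33 within the small ring class, and within the large ring class both groups lay at the floor. On the other side were the retinol dehydrogenase gene Rdh11 at -0.47, Zfp280d at -0.42 and Dmac2l at -0.68 (adjusted p = 0.268 each). For each of these 6 genes all 5 fish oil rats lay on that side of the corn oil mean.

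No probe passed in limma for fish oil against corn oil at 12 h (0, with 528 at an unadjusted p under 0.05), and no list passed camera. The nearest lists shared adjusted p = 0.0933. Of these, fatty acid oxidation (15 of 18 members positive), lipogenesis and adipocyte markers pointed up, and fibroblast, immediate early and unfolded protein response genes pointed down. Adjusted over the list alone, 1 adipocyte gene was higher and 1 immediate early gene was lower. Cpt1a, which encodes an enzyme for the entry of fatty acids into mitochondria, stood at 0.26 (SE 0.12, adjusted p = 0.592). The DNA repair gene Mgmt stood at 0.00 (SE 0.24) and Cdkn1a at -0.02 (SE 0.10). Without rat 103 a single probe passed, Dmac2l (adjusted p = 0.0101). The fatty acid oxidation list passed without rat 203 (adjusted p = 0.00826), and macrophage markers, lower in fish oil, without rat 202 (adjusted p = 0.0267). With the first array of each rat alone 20 probes passed, among them Fabp4 (adjusted p = 0.0452), Rgs4 (adjusted p = 9.05e-06), Gfpt2 (0.0211) and Dmac2l (0.0477). In that setting large ring arrays with low median signals, 163 and 177, stand for corn oil rats 102 and 103. Small ring arrays stand for every fish oil rat, so these calls mix diet with scan class. Within the large ring class the Rgs4 difference was 0, with both groups at the floor.

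Between olive oil and corn oil rats at 12 h, matrix genes of fibroblasts were lower in olive oil. All 3 measured members were negative, with a median of -0.45 (0 lower over all probes, 1 lower adjusted over the list alone, camera adjusted p = 0.00408). The list did not pass at adjusted p = 0.0925 with an estimated correlation, and passed by fry (0.0174). The collagen gene Col1a1 lay at 8.29 ± 0.33 (n = 5) in olive oil and 9.02 ± 0.30 (n = 5) in corn oil rats, a difference of -0.73 (SE 0.15, adjusted p = 0.163), Col6a1 at -0.44 (adjusted p = 0.498) and Sparc at -0.45 (adjusted p = 0.617). With scan class as a block the list passed (adjusted p = 0.0265), and within the small ring class (2 and 4 rats) its median was -0.49. With that block oxidative phosphorylation (adjusted p = 0.0315) and ribosomal protein genes (adjusted p = 0.0265) were lower in olive oil too. The fibroblast list was lost without rat 104 (adjusted p = 0.0556) or 306 (0.112). Cell cycle genes, lower in olive oil, passed without rat 103, 105, 106, 301, 302 or 305 (0.00597 to 0.0458), and oxidative phosphorylation without rat 106, 301 or 305 (0.0341 to 0.0476). Cell cycle genes passed with the mean of a gene's probes (0.0449), and under median scaling oxidative phosphorylation and ribosomal protein genes were lower (9.83e-06 each).

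No single probe passed in limma for olive oil against corn oil at 12 h (0, with 590 at an unadjusted p under 0.05). Prep, which encodes prolyl endopeptidase, stood at 1.43 (SE 0.32, 2.69-fold), Arhgef7 at 0.56 and C10h1orf35 at 0.40, and Tsc22d4 at -1.75 (SE 0.43) and the clock output gene Dbp at -0.81 (SE 0.20), all with adjusted p = 0.163 and with all 5 olive oil rats on that side of the corn oil mean. Cpt1a, Mgmt and Cdkn1a stood at 0.13, 0.12 and 0.02, with adjusted p-values of 0.745, 0.875 and 0.961. This count moved with the treatment of arrays, to 20 with the first array of each rat, 377 with array quality weights, 59 without olive oil rat 306, 1 without rat 103, 1 without rat 304 and 10 without the 6 high-background arrays, which are all from late rats and enter through the shared estimate of the spread. Without rat 306 those that passed included C10h1orf35 (adjusted p = 0.0212), Prep, Arhgef7 and Col1a1 (0.0467 each), and without rat 304 the 1 was Col1a1 (0.0122). Prep, Arhgef7, C10h1orf35, Col1a1 and Tsc22d4 passed with weights, with the first array and without the high-background arrays, and Dbp with weights (0.0147).

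Between fish oil and olive oil rats at 12 h, cell cycle genes were higher in fish oil as a list. All 9 measured members were positive, with a median of 0.32 (0 higher over all probes, 2 higher adjusted over the list alone, camera adjusted p = 0.000455). The call was lost at adjusted p = 0.746 with an estimated correlation and was absent by fry (0.368). Mki67 lay at 10.31 ± 0.51 (n = 5) in fish oil and 9.54 ± 0.17 (n = 5) in olive oil rats, a difference of 0.77 (SE 0.20, 1.71-fold, adjusted p = 0.453), Ccna2 at 0.59, Cdk1 at 0.38 and the mitotic kinase gene Aurkb at 0.39, with adjusted p-values of 0.54, 0.584 and 0.639. With scan class as a block the list passed (adjusted p = 0.00154), as did ribosomal protein genes, higher in fish oil (adjusted p = 0.00945). Its median was 0.46 within the small ring class (5 fish oil and 2 olive oil rats) and -0.14 within the large spots class (1 and 3 rats). The call was lost without rat 304 (adjusted p = 0.0566), and fatty acid oxidation genes, higher in fish oil, passed without rat 203 (0.0313). Under median scaling oxidative phosphorylation (0.00602) and ribosomal protein genes (0.000135) were higher in fish oil.

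The melatonin receptor gene Mtnr1b stood at 0.53 (SE 0.11, adjusted p = 0.255) and the mitochondrial carrier gene Slc25a34 at 0.46 in that comparison. On the lower side were Med20 at -0.43, the aldose reductase gene Akr1b1 at -0.62 and the nuclear pore gene Nup88 at -0.41, with adjusted p-values of 0.279, 0.279 and 0.453, and all 5 fish oil rats lay on that side of the olive oil mean for each. No probe passed in limma (0, with 484 at an unadjusted p under 0.05). Cpt1a, Mgmt and Cdkn1a stood at 0.13, -0.12 and -0.04. With array quality weights 132 probes passed, among them Mtnr1b, Slc25a34, Akr1b1 and Nup88 (0.00635 to 0.00843), and without rat 306 there were 2. The F test over the 3 diets at 12 h called 0 probes in limma, with 599 at an unadjusted p under 0.05, and it called 1 without rat 103 and 2 without rat 304.

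At 10 wk, 4 genes were lower in fish oil than in corn oil rats. Arfip1, which encodes a binding partner of small GTPases, fell by 0.77 (SE 0.14, 1.70-fold, adjusted p = 0.0364), and Top2b, which encodes a DNA topoisomerase, by 0.75 (SE 0.13, adjusted p = 0.0401). Abi1, which encodes a regulator of the actin cytoskeleton, lay at 9.12 ± 0.68 (n = 4) against 10.12 ± 0.16 (n = 5), a difference with SE 0.20 (adjusted p = 0.0417). Ctsc, which encodes the lysosomal protease cathepsin C, fell by 0.67 (SE 0.13, adjusted p = 0.0417), from 10.17 ± 0.18 to 9.50 ± 0.30. For each of them all 4 fish oil rats lay below the corn oil mean.

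These were the only probes of 6378 that passed in that comparison (4 lower and 0 higher, with 685 at an unadjusted p under 0.05). All 4 calls were lost without fish oil rat 234 or 236 or corn oil rat 132, 135 or 136, where the median difference of the 4 genes was -0.70, -0.64, -0.70, -0.75 and -0.74, against -0.76 with all rats. They were lost too with scan class as a block, where Arfip1, Top2b, Abi1 and Ctsc stood at -0.89, -0.82, -1.12 and -0.72 (adjusted p-values of 0.11 to 0.181). Under median scaling they stood at -0.73, -0.75, -0.97 and -0.63 (0.1 to 0.127), and with array quality weights at -0.65, -0.63, -0.75 and -0.57 (0.066 to 0.135). Arfip1 and Top2b were lost with the rat as a random block (0.0555 each), Top2b with the first array of each rat (0.0611) and in the deposited values, where constants stand in for its probe (0.104), and Abi1 without a filter on dim probes (0.052). Without corn oil rat 134 only Arfip1 and Top2b stood. The count was 27 without rat 131, 34 without rat 232 and 63 without rat 233, and these kept all 4. Within the large ring class (4 fish oil and 3 corn oil rats) the differences were -0.80 for Arfip1, -0.75 for Top2b, -1.06 for Abi1 and -0.60 for Ctsc.

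**Figure D4:**
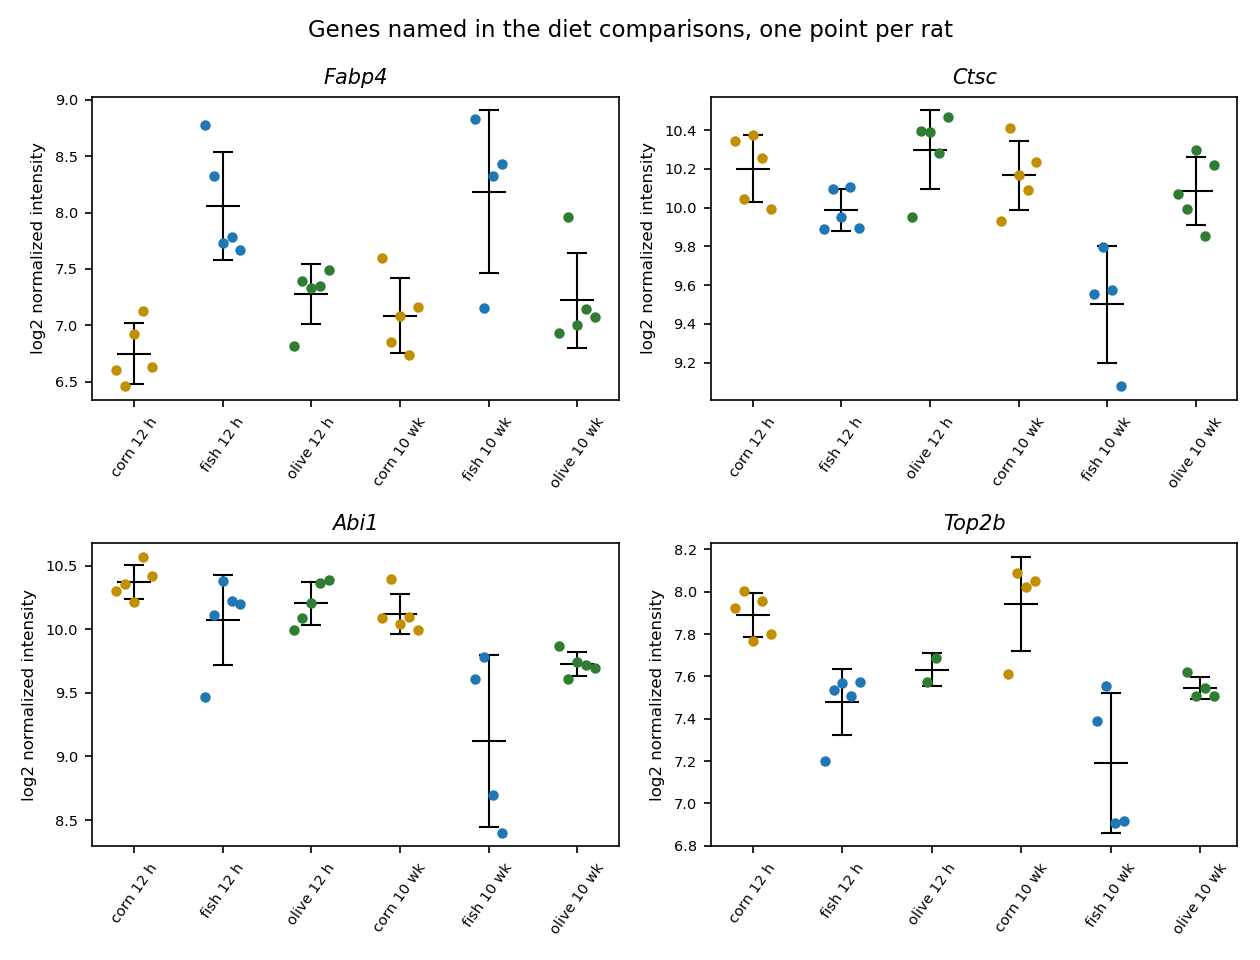
Log2 normalized intensity (vertical axes) of Fabp4, Ctsc, Abi1 and Top2b in the 6 groups (horizontal axes), 1 point per rat, with the mean and SD of each group as bars. Ctsc, Abi1 and Top2b were lower in late fish oil than in late corn oil rats, and Fabp4 did not pass in any diet comparison (8.18 ± 0.72 in late fish oil, 7.09 ± 0.33 in late corn oil rats).

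Genes of the unfolded protein response were lower in late fish oil than in corn oil rats as a list. All 9 measured members were negative, with a median of -0.24 (0 lower over all probes, 1 lower adjusted over the list alone, camera adjusted p = 0.0255). The list did not pass at adjusted p = 0.321 with an estimated correlation, and passed by fry (0.0462). Pdia4, which encodes a protein disulfide isomerase of the endoplasmic reticulum, lay at 9.93 ± 0.09 (n = 4) against 10.65 ± 0.32 (n = 5), a difference of -0.72 (SE 0.16, adjusted p = 0.0697). Herpud1 stood at -0.48, Dnajc3 at -0.24 and Chac1 at -0.43, with adjusted p-values of 0.353, 0.562 and 0.721. The block gave adjusted p = 0.03 for the list, and its median within the large ring class was -0.23. The list was lost without corn oil rat 134 (adjusted p = 0.208) or fish oil rat 232 (0.0563), 234 (0.054) or 236 (0.0564), where its median was -0.19, -0.27, -0.23 and -0.23. In this comparison probes named for full mRNAs had a median of -0.07 and those named for ESTs 0.03. Among the large ring arrays of late fish oil rats, those of rat 234 (-18.1 and -17.7) and rat 236 (-20.5) lay apart on component 2 from rats 232 (-9.35) and 233 (-9.83).

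Other genes near the threshold in late fish oil against corn oil rats were Fabp4 at 1.10 (SE 0.27, 2.14-fold, adjusted p = 0.0783), Mtnr1b at 0.48 and Dcun1d4 at 0.44 (adjusted p = 0.0699 for both). The amyloid precursor gene App stood at -0.87, the mitochondrial chaperone gene Hspd1 at -0.84 and Ssbp3 at -0.79 (adjusted p = 0.0689 each). Cpt1a, Mgmt and Cdkn1a stood at 0.06, 0.03 and 0.11, with adjusted p-values of 0.944, 0.989 and 0.8. Without the 6 high-background arrays 40 probes passed, 12 higher and 28 lower, and these included Fabp4, App, Hspd1 and Pdia4 (adjusted p = 0.0431 each). App, Hspd1 and Ssbp3 passed with the stricter filter (0.0482 each) and without rat 131, 232 or 233 (0.00427 to 0.0486), and Fabp4 and Pdia4 without rat 131 or 233 (0.00427 to 0.0463). Adipocyte markers, higher in fish oil, passed as a list without rat 233 (0.024).

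Of the 6 diet comparisons, late olive oil against corn oil had the fewest probes at an unadjusted p under 0.05, 147. Irf9, which encodes a component of the interferon-activated transcription factor, stood at -0.32 (SE 0.10), the ribonuclease inhibitor gene Rnh1 at -0.45 (SE 0.13) and Chrac1 at -0.29, and the zinc transporter gene Slc39a14 stood at 0.41 (SE 0.15), Dcun1d4 at 0.28 and Mrps27 at 1.27 (SE 0.45), all with adjusted p = 0.999 and all 5 olive oil rats on that side. Another probe for Mrps27 had the opposite sign. No probe passed in limma (0, with 147 at that unadjusted p where 318.9 would fall by chance) and no list passed camera, the nearest being lipogenesis and ribosomal proteins, both higher (adjusted p = 0.0786). Both passed with scan class as a block, as did the interferon list, which was lower in olive oil (adjusted p = 0.0496 each). Ribosomal proteins passed without rat 332 (adjusted p = 0.0179), and both lists and immediate early genes, lower, without rat 136 (0.0486 each). Cpt1a, Mgmt and Cdkn1a stood at 0.17, -0.04 and -0.09, each with adjusted p = 0.999.

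Between late fish oil and olive oil rats, unfolded protein response genes were lower in fish oil, with 8 of 9 members negative and a median of -0.25 (0 lower over all probes, 1 lower adjusted over the list alone, camera adjusted p = 0.00823). The call was lost at adjusted p = 0.179 with an estimated correlation and absent by fry (0.131). Pdia4 stood at -0.59, Chac1 at -0.86, Dnajc3 at -0.30 and Herpud1 at -0.31, with adjusted p-values of 0.57 or above. Adipocyte markers were higher in fish oil (3 of 3 positive, 1 higher adjusted over the list alone, camera adjusted p = 0.0367, adjusted p = 0.206 with an estimated correlation, fry 0.283). Fabp4 stood at 0.96 (SE 0.27, 3 of 4 fish oil rats above the olive oil mean), Adipoq, which encodes the adipocyte hormone adiponectin, at 0.60 (SE 0.33), and Pparg at 0.01. Both lists passed with scan class as a block (adjusted p = 0.00227 and 0.00823), and their medians within the large ring class (4 and 4 rats) were -0.15 and 0.85. With that block cell cycle genes were lower in fish oil too (adjusted p = 0.0195), and under median scaling these were lower and colonocyte genes higher (0.025 each). The adipocyte list was lost without rat 232, 234, 334, 335 or 336 (0.053 to 0.368). Cell cycle genes, lower, passed without rat 234, 236, 332 or 333 (0.00567 to 0.0386), colonocyte genes, higher, and ribosomal protein genes, lower, without rat 234, 236 or 332 (0.00749 to 0.0358), and interferon genes, higher, without rat 236 (0.00749). Rats 234 and 236 lay apart on component 2, as given above for the large ring arrays. Olive oil rat 335 lay apart there in the opposite direction, at 8.79 against -9.63 to -12.8 for the other late olive oil arrays of that class. On component 1 the large ring arrays of rats 234, 236 and 335 lay on the same side, at -10.2 to -17.3. The other late fish oil and olive oil arrays of that class lay at -4.66 to 4.82.

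No probe passed in limma for late fish oil against olive oil (0, with 302 at an unadjusted p under 0.05, and 2 without rat 232, among them Add3 at adjusted p = 0.00741). Tsc22d4 stood at 1.80 (SE 0.45, 3.47-fold), at 10.35 ± 0.71 (n = 4) against 8.55 ± 0.32 (n = 5), the adhesion gene Ceacam1 at 0.64, Ctsc at -0.59, Add3 at -0.63 and Hspd1 at -0.72, all with adjusted p = 0.57 and all 4 fish oil rats on that side. Tsc22d4 passed with the first array of each rat (0.0382) and, with Ctsc, with array quality weights (0.0465 each). Cpt1a, Mgmt and Cdkn1a stood at -0.11, 0.07 and 0.20. The F test over the 3 diets at 10 wk called 0 probes in limma, with 412 at an unadjusted p under 0.05, and it called 4 without rat 131, 5 without rat 232 and 22 without rat 233.

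Whether diet differences changed between the time points was tested directly. The olive oil against corn oil difference in fibroblast matrix genes was higher at 10 wk than at 12 h, with 3 of 3 members positive (median 0.58, 1 higher adjusted over the list alone, camera adjusted p = 0.0151, adjusted p = 0.185 with an estimated correlation). The fish oil against olive oil difference in cell cycle genes was lower at 10 wk, with 9 of 9 members negative (median -0.37, 2 lower adjusted over the list alone, camera adjusted p = 1.73e-06, adjusted p = 0.475 with an estimated correlation, fry 0.629). Both lists passed with scan class as a block (adjusted p = 0.0148 and 3.49e-07). Oxidative phosphorylation (adjusted p = 0.0148 and 0.0168) and ribosomal protein genes (adjusted p = 0.000955 and 0.000682) passed with it too, higher in the olive oil against corn oil interaction and lower in the fish oil against olive oil one. The fibroblast list was lost without rat 104 (adjusted p = 0.0704) or 306 (0.104). In the olive oil against corn oil interaction cell cycle genes passed, higher, without rat 106, 132, 301, 305 or 332 (0.0154 to 0.04), ribosomal protein genes without rat 134, 301, 302, 305 or 332 (0.0168 to 0.0499) and oxidative phosphorylation without rat 134 (0.0295) or 305 (0.0443). In the fish oil against olive oil one ribosomal protein genes passed, lower, without rat 201, 202, 234, 236, 301, 302, 305, 332 or 336 (0.002 to 0.0411). In the fish oil against corn oil one cell cycle genes passed, lower, without rat 102, 234 or 236 (0.0252 to 0.036) and cholesterol synthesis, lower, without rat 102 (0.0174). For Mki67 the fish oil against olive oil interaction was -0.92 (adjusted p = 0.996). No single probe passed in limma's F test for the interaction (0, with 260 at an unadjusted p under 0.05), where the smallest adjusted p was 0.938. The pairwise interactions called 0 probes each too. Their smallest adjusted p-values were 0.963 for fish oil against corn oil, 0.640 for olive oil against corn oil and 0.996 for fish oil against olive oil.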

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

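The tests of scan class, of repeat array 3 of rat 236 and of rat 104, the reading of single rats by the size of the differences, the lists without single rats, the look at what the splits separated, and the fits with scan class as a block, without the 6 high-background arrays and without that array of rat 236, were chosen only after the result was seen.

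The fall of p53 targets and the other differences between 10 wk and 12 h averaged over diets were weighed against the scan classes. Of 2324 probes called without the 6 rats that have large spots arrays, 85.2% had the same sign within that class, against 62.2% of the probes not called, and 2049 probes passed with scan class as a block, which argues against scan class as the whole cause. The 6 high-background arrays of late rats 136 and 236 are not the whole cause either, since 2466 probes passed without them. Of 100 splits of the rats only 1, the real one, gave as many as 2355 probes and the highest other gave 813, which argues against chance. Age, number of injections and time on diet change together with the hours or weeks since the injection, and these differences stay open and untested.

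The lower Arfip1, Top2b, Abi1 and Ctsc in late fish oil rats were weighed against single rats and probe kinds. Of these 4 calls, 0 stood without rat 234, 0 without rat 236 and 0 without corn oil rat 132, 135 or 136. The loss without rat 234 or 236 was the outcome predicted beforehand if 1 or 2 late fish oil rats caused the calls. The median log2 difference of the 4 genes, -0.76 with all rats, was -0.70 without rat 234 and -0.64 without rat 236. The calls thus ended with little change in the differences. That reading by size was added once the values were known, and the part of single rats in the calls stays open. Probes named for full mRNAs had a median difference of -0.07 (1780 probes) and those named for ESTs 0.03 (4598 probes). The gap of -0.102 lay just past the bound of 0.1 set beforehand for RNA or labelling yield, which stays open. It cannot be weighed against the 4 differences, since these were picked as extremes and the gap is between medians over all probes. Repeat array 3 of rat 236 differed from the high-background arrays of corn oil rat 136 by a median SD of 0.278 and from its own rat's by 0.42, while the other high-background arrays of either rat differed within the rat by 0.0656 to 0.125, so whose RNA it holds is undecided, and without it 0 probes passed while Arfip1, Top2b, Abi1 and Ctsc stood at -0.85, -0.82, -1.08 and -0.71 (adjusted p = 0.0551 each), each larger in size than with it. Of 100 splits 10 gave at least 4 probes, chance cannot be excluded, and the highest other split gave 46 and set rats 135, 136, 234 and 236 apart, with 57.5% of the variance of component 1 between its groups, the most of the 100 splits, which points to a structure of the samples. Rats 136 and 236 hold the 6 high-background arrays, which lie at component 1 scores of -20.4 or below and enter the mean scores of these rats. That split had 15.1% of the scan class differences between its groups, against 5.59% for the real one. An effect of fish oil itself stays among the open explanations.

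Corn oil rat 104 had low p53 targets at 12 h, with Phlda3 at 7.09 against 9.09 ± 0.32 (n = 4) in the other corn oil rats, Ccng1 at 11.29 against 12.51 ± 0.26 and Plk2 at 8.34 against 9.15 ± 0.29, though Gadd45a lay at 11.87 against 11.59 ± 0.25. A single poor array is argued against, as Phlda3 lay at 7.16 and 7.03 on its 2 arrays, both below the midpoint of 8.06 between the times. On a scale from the late mean at 0 to the 12 h mean at 1, its median over the p53 targets was 0.0238, where other 12 h rats lay at 0.522 to 1.55 and late rats at -0.31 to 0.248, which restates those low levels and decides nothing about a weaker response to azoxymethane in that rat. Over all probes called between the times its median was 0.693, between the late rats (up to 0.612, or 0.322 without rat 134) and the other 12 h rats (from 0.77), so a late rat labelled 12 h is undecided. The injection itself was not measured, and a weaker response and a missed or smaller dose stay open and untested.

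For the remaining comparisons, of 100 splits each, only the real one gave as many probes for time in corn oil (193, highest other 10), in fish oil (776, highest other 428) and in olive oil rats (852, highest other 510), which argues against chance there. These splits do not separate time from scan class. The real split had 26.0% of the scan class differences between its groups in corn oil, 63.2% in fish oil (2 of the 100 splits had as much) and 37.5% in olive oil rats. That with 428 had 32.6%, and that with 510 had 50%, the most of its 100. These splits kept most of the real grouping by time. That with 428 placed only rat 201 with the other time, that with 510 only rats 306 and 333, and that with 10 only rats 104 and 136. Their counts therefore hold part of the time difference and do not measure scan class alone. Where the real count was 0 all 100 splits gave as many by construction, so they say nothing about chance. In these the highest other split gave 1 probe for fish oil against corn oil, 112 for olive oil against corn oil and 278 for fish oil against olive oil at 12 h, and 1 for olive oil against corn oil and 2 for fish oil against olive oil at 10 wk. The F tests gave up to 6 at 12 h, 170 at 10 wk and 81 for the interaction. Of the splits with large counts where the real count was 0, that with 112 had 58.9% of the scan class differences between its groups, more than the others of the 100, and with scan class as a block the real count stayed 0. That with 278 had 44.9% of the variance of component 1 between its groups (3 of the 100 splits had as much) and that with 170 had 83.0%, the most of the 100. What the split with 81 separated was not examined.

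In 2 lists the diet difference itself differed between the time points by camera. The olive oil against corn oil difference in fibroblast matrix genes was higher at 10 wk (adjusted p = 0.0151, 3 of 3 members, adjusted p = 0.185 with an estimated correlation, 0.0704 without rat 104 and 0.104 without rat 306). The fish oil against olive oil difference in cell cycle genes was lower at 10 wk (adjusted p = 1.73e-06, 9 of 9 members, and adjusted p = 0.475 with an estimated correlation).

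For 104 named genes, the gap between the highest or lowest rat of a group and its nearest neighbour was divided by the group's range. It passed Dixon's 95% value in 49 of 623 groups, where chance gives about 1 in 20, or 31.15, and most often in rats 335 (5 times) and 206 (4 times). In that share of the range, late olive oil rat 335 stood below its group for Prep (0.903), Arhgef7 (0.81) and Rnh1 (0.736) and above it for Mgmt (0.757) and Ier2 (0.723). Early fish oil rat 206 stood high for Cd36 (0.875) and Cnn1 (0.884), where 3 of the 5 rats lay tied at the floor, which sets these shares in part, and low for Rgs4 (0.838) and Clic4 (0.79). Early olive oil rat 304 stood high for Cd36 by the whole range (1), the other 4 rats lying at the floor. Arrays at the floor also enter the groups of rats 206 and 136 for Rgs4, 236 for Cd36, 301 for Cnn1 and 102 for Slc10a1.

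Among the other corn oil rats at 12 h, rat 102 was high for Slc10a1 (0.714), Ephx1 (0.724) and Ier2 (0.731), rat 103 for Alox5 (0.772) and rat 105 for Ceacam1 (0.736) and Fabp6 (0.834). Rat 104 was low for Phlda3 (0.722) and Tsc22d4 (0.75), and rat 106 for Ucp2 (0.717) and Rps18 (0.773). In fish oil at 12 h, rat 201 was low for Top2b (0.827) and Bak1 (0.767), and rats 202 and 203 were high, the first for Pdia5 (0.841) and Bmal1 (0.83), the other for Col1a1 (0.748) and Tsc22d4 (0.882). In olive oil at 12 h, rat 301 was low for Fabp4 (0.776) and App (0.817) and high for Cnn1 (0.812), rat 302 low for Acsl3 (0.855) and rat 306 high for Tyms (0.803).

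At 10 wk, corn oil rat 131 was low for Top2b (0.866) and high for Rps3a (0.806), rat 132 was high for Abi1 (0.747) and rat 134 for Med20 (0.748) and Clic4 (0.909). Rat 135 was low for Chrac1 (0.84) and Acsl3 (0.744), and rat 136 was low for Rgs4 (0.742) and Prep (0.749) and high for Adipoq (0.865). Late fish oil rat 232 was high for Trpv6 (0.88), and rat 236 low for Prep (0.847) and Cd36 (0.867). Late olive oil rat 332 was low for Fasn (0.879) and high for Cdhr5 (0.731), rat 333 high for Fabp4 (0.796) and Cpt1a (0.749) and rat 334 low for Herpud1 (0.823).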

How the results depend on the processing

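The fits with scan class as a block, without the 6 high-background arrays, without repeat array 3 of rat 236, with a signal strength filter and with the deposited values less the replaced probes, and the lists without single rats, were chosen after seeing the data. No paired analysis was possible because the replicate numbers in the labels mark repeat arrays of a rat and rats are not shared between groups. A slide or scan date block was not run, as the files give neither. A lower floor and trend with robust moderation moved no count of probes by over 1.5 times. Dim probes limit what can be seen, since the median signal above background was 163 to 685 per array. Where no cause is named below, the cause was not tested.

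For late fish oil against corn oil 4 probes passed, and 0 did under median scaling, with array quality weights, with scan class as a block, without that array of rat 236 and with the groups compared alone. Without a filter on dim probes there were 7, without the 6 high-background arrays 40, in the deposited values 60 and in these without the replaced probes 39. For time averaged over diets (2355) the stricter filter gave 1449 of the 4225 probes it tested, all among the 2355. The deposited values gave 1237, of which 885 were higher and 352 lower against 1226 and 1129, and without the replaced probes 1226, of which 901 were higher. In the deposited values late corn oil rat 131 has a median of 2.02, against 1.04 to 1.06 on the other arrays. No further scaling was applied, so this offset raises the late corn oil mean and the spread between rats. It enters every deposited count given here, and its share in them was not tested.

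For time in corn oil rats (193) the count was 326 without a filter, 107 with the stricter filter, 341 with all 43 arrays and the rat as a random block, 415 with weights and 836 with the scan block. In fish oil rats (776) it was 447 with the stricter filter, 164 in the deposited values, 154 in these without the replaced probes and 272 with the groups compared alone. In olive oil rats (852) it was 497 with the stricter filter, 2321 with weights, 141 in the deposited values, 143 in these without the replaced probes and 566 with the scan block.

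Where limma called 0 probes, other settings called some. Fish oil against corn oil at 12 h gave 3 without a filter, 20 with the first array of each rat and 6 in the deposited values. The first arrays of corn oil rats 102 and 103 are of the large ring class, and those of the other diets at 12 h are not. Olive oil against corn oil at 12 h gave 1 without a filter, 20 with the first array, 2 with the random block, 377 with weights, 16 in the deposited values, 10 without the high-background arrays and 8 with the groups compared alone. Fish oil against olive oil at 12 h gave 132 with weights and 10 in the deposited values. At 10 wk, olive oil against corn oil gave 16 in the deposited values and 9 without the replaced probes. Fish oil against olive oil gave 1 without a filter, 1 with the first array, 3 with weights, 14 in the deposited values and 6 without the replaced probes. The F test at 12 h gave 4 without a filter, 21 with the first array, 411 with weights, 18 in the deposited values, 5 without the high-background arrays and 6 with the groups at 12 h alone. The F test at 10 wk gave 1 without a filter, 32 in the deposited values and 16 without the replaced probes, and the interaction 7 with the first array, 10 in the deposited values and 4 without the replaced probes. In the comparisons at 12 h the deposited values without the replaced probes gave 0 throughout. The signal strength filter removed no probe and so equals no filter (3, 1, 7, 1, 326, 4 and 1 probes in the same comparisons).

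Leaving out 1 rat at a time gave 0 to 1 probes for fish oil against corn oil, 0 to 59 for olive oil against corn oil and 0 to 2 for fish oil against olive oil at 12 h, highest without rats 103, 306 and 306. At 10 wk these were 0 to 63 (without rat 233), 0 to 0 and 0 to 2 (without rat 232). Time gave 2020 (without rat 234) to 2482 (without rat 134) averaged over diets, 65 (without rat 103) to 266 (without rat 104) in corn oil, 338 (without rat 234) to 857 (without rat 232) in fish oil and 456 (without rat 334) to 926 (without rat 306) in olive oil rats. The F tests gave 0 to 2 at 12 h (without rat 304), 0 to 22 at 10 wk (without rat 233) and 0 to 0 for the interaction.

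No list passed with an estimated correlation (0 in every contrast). For olive oil against corn oil at 12 h 1 list passed, 2 with the mean of a gene's probes, 3 under median scaling and 3 with the scan block. For fish oil against olive oil at 12 h the 1 became 0 by fry, 3 under median scaling and 2 with the block. At 10 wk, 3 passed with the block for olive oil against corn oil (0 without), and for fish oil against olive oil the 2 became 0 by fry and 4 under median scaling. For time averaged over diets the 3 became 15 by fry and 5 with the mean of probes. In corn oil the 4 became 2 by fry and 0 with the block, in fish oil the 0 became 4 by fry and 2 with the block, and in olive oil the 5 became 13 by fry. Leaving out 1 rat at a time gave 0 to 1, 0 to 3 and 0 to 2 lists at 12 h for fish oil against corn oil, olive oil against corn oil and fish oil against olive oil, and 0 to 2, 0 to 3 and 1 to 6 in that order at 10 wk. For time it gave 1 to 5 averaged over diets, 1 to 5 in corn oil, 0 to 0 in fish oil and 2 to 6 in olive oil rats, and for the interactions 0 to 2, 0 to 4 and 1 to 2 in the order of the diets above, where all rats gave 0, 1 and 1. The calls that passed without each rat in turn were p53 targets over time (averaged, in corn oil and in olive oil), unfolded protein response in late fish oil against olive oil and cell cycle in that interaction.

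Of 135 results for named genes, Cd36, Rps3a, Rps18 and Rps19 over time turned to -0.20 each in the deposited values. By construction this is the array scaling alone, since constants stand there on all arrays of a diet. Of 122 diet calls in those values 65 (53.3%) lay on replaced probes, which make up 18.6% of those tested, a fit without the replaced probes called 54, and 3 of the 122 were among the 4 of the spot values. No other call among them changed direction. Calls were lost for 11 under median scaling, 15 with the scan block, 21 in the deposited values, 12 in these without the replaced probes, 8 with weights, 6 with the first array, 5 with the random block, 2 without a filter and 1 with trend and robust moderation, while 4 were lost without repeat array 3 of rat 236. Calls were gained for 13 without the high-background arrays, 12 with weights, 11 with the first array and 4 with the random block.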
